A study of Mus musculus with 57 samples.

How the data were processed

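RNA of Lewis lung carcinoma (LLC) tumors grown in male young and old mice was measured on Illumina Mouse WG-6 BeadArrays, 1 tumor per array per the labels. The labels give 57 arrays in 4 groups, and the design text counts 60 tumors. The other 3 are not analysed here. Groups were taken from the sample labels: young unirradiated (18), young proton-irradiated (10), old unirradiated (19) and old proton-irradiated (10). Irradiated tumors received 0.5 Gy of protons 3 times. The unirradiated tumors belong to 2 control arms named in the labels, 0Gyx3 (called the x3 arm here, read as 3 fractions of 0 Gy) and acute. Young tumors have 9 controls in each arm, and old tumors have 9 in the x3 arm and 10 in the acute arm. For 9 of the 10 old acute-arm controls, 1 label field names the arm and no dose, while the source and treatment fields give 0 Gy and none. They were used as unirradiated.

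The deposited non-normalized table holds, per the file headers, an averaged bead signal (an intensity) and a detection p-value for each probe and array. Its signals have no background subtracted. The steps of the detection p-values imply 936 negative controls per array. The value table of the authors holds a signal intensity on a linear scale. Per the design text, the authors subtracted background and applied rank-invariant normalization in GenomeStudio (version not given in the sources used here), filtered out average signals under 10, and ran a one-way ANOVA with Bonferroni correction in MeV. In the deposited value table each array was its own non-normalized signal times 1 factor (0.402 to 4.21) plus an offset, to within 0.0251 signal units. The negative-control level stayed at 119 to 146 and the lowest value was 48.9, so a floor of 10 removed nothing there.

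Log2 values were computed from the non-normalized signals with neqc of limma 3.58.1 (R 4.3.3, version 1.17.8 of data.table). This function fits normexp background from negative controls inferred from the detection p-values, normalizes by quantiles and adds an offset of 16. Of 45281 probes, 34885 were paired with 1 gene symbol, 18 with several and 10378 with none. Entrez identifiers matched the reference for 34807 probes and changed 0 symbols. Probes with detection p under 0.01 on at least 10 arrays were kept, 16824 in all, of which 14428 had 1 symbol. The brightest kept probe stood for each gene, which left 9256 genes, 3539 of them with more than 1 kept probe. Among genes with more than 1 called probe, 239 of 910 had called probes in both directions for age, 0 of 9 for protons in young tumors and 5 of 121 for protons in old tumors.

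Depth for these arrays is the share of probes detected, given per set in the results, and the number of arrays limits the precision. All 57 arrays were fitted together in limma (lmFit, contrasts.fit, eBayes) with the 4 groups, and p-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. A second fit with 6 groups compared the control arms. P-values treat the arrays as separate tumors, as the labels name them. Differences in the share of probes detected were tested by exact two-sided permutation, 6 tests in all, with Benjamini-Hochberg adjustment. The 36 gene lists (20 pathway lists and 16 cell type lists) were fixed before the data were examined, and 34 of them had at least 3 measured genes. They were tested with camera at a preset inter-gene correlation of 0.01, and also with an estimated correlation and with fry. Where a gene was detected on no array of a group, its fold is given as a bound, at least N-fold, from the detection limit of those arrays. Where few arrays of a group detected a gene (at most 3 for Bmx, Mup2, Nfya, Syne3, Ppp1r9a, Mlxipl, Hspb1, Hspa1a and Hsf2), the fitted difference is not an exact fold.

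Named genes were chosen by a rule also fixed before the data were examined. For the age effect in unirradiated tumors and the proton effects, it takes the 8 largest rises and the 8 largest falls among called genes whose sign was the same against each control arm alone. It adds up to 3 called members of each of up to 6 called lists, and the values of Cdkn1a, Mdm2, Vegfa, Tgfb1 and Mki67. For the interaction, the age effect in irradiated tumors and the control arms, it takes the 5 smallest p-values. Symbols made of LOC or Gm with digits, or ending in Rik, were counted and not named: 70 for age, 5 for protons in young tumors and 12 for protons in old tumors. Members of lists called in the other comparisons that involve irradiated old tumors were added by the list part of the rule after values were seen. Other genes named for the libraries that stand apart were likewise chosen after their values were seen. Lung markers were listed after those libraries were noticed.

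The steps were tested on simulated data. With independent normal values drawn from the mean and spread of each gene and 200 of 9256 genes changed, limma recovered 83.6% of the 1.5-fold changes for the age effect, 67.2% for protons in young tumors, 82.1% for protons in old tumors and 41.8% for the interaction. It called 5, 13, 8 and 3 unchanged genes. A list shifted by 0.5 was the 1 list called by camera. The simulated values held no control arms, no libraries that stand apart and no correlation between genes. They therefore do not show how many false calls such structure gives.

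Alternatives tried were the value table of the authors, no background correction, median scaling in place of quantiles, no probe filter, a filter on all arrays, the mean of all probes of a gene, array weights, a fit of only the groups compared, the replicate number as a block, each control arm alone, the arm as a covariate, a minimum change of 1.5-fold, the one-way ANOVA named in the design text, and leaving out each library in turn. Chosen after seeing the data were fits without the 2 libraries that hold lung transcripts, without these and a library rich in skeletal muscle transcripts, with the share of probes detected as a covariate, and with x3-arm controls but without those 2 libraries. Chips were not fitted as a batch because the files used here give no chip numbers. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.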

Results

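Transcript levels were measured in 57 LLC tumors (Lewis lung carcinoma, a mouse tumor line) on 1 array each. Young mice gave 18 unirradiated and 10 proton-irradiated tumors, and old mice gave 19 and 10. Irradiated tumors had received 3 proton doses of 0.5 Gy. The median non-normalized signal per array ranged from 89.2 to 208. The share of probes detected was 34.7% ± 1.74 (SD, n = 9) in young acute-arm controls, 34.0% ± 0.798 (SD, n = 9) in young x3-arm controls and 34.3% ± 0.694 (SD, n = 10) in young irradiated tumors. In old tumors it was 32.9% ± 1.30 (SD, n = 10) in acute-arm controls, 28.6% ± 3.13 (SD, n = 9) in x3-arm controls and 29.3% ± 2.11 (SD, n = 10) after irradiation. Old x3-arm controls differed from old acute-arm controls by -4.32 points (exact permutation p = 0.00139, adjusted p = 0.00417) and from young x3-arm controls by -5.49 points (exact permutation p = 8.23e-05, adjusted p = 0.000494). Old acute-arm controls differed from young ones by -1.83 points (exact permutation p = 0.014, adjusted p = 0.028). Irradiated old tumors did not differ detectably from old x3-arm controls (0.736 points, exact permutation p = 0.547), nor irradiated young tumors from young x3-arm controls (0.266 points, exact permutation p = 0.444).

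Some libraries held transcripts typical of other tissues. Old unirradiated libraries 6 and 7, both x3-arm controls, held transcripts typical of lung. Scgb1a1, the secretory protein of airway club cells, stood at log2 14.49 and 14.54 in them, against a median of 4.65 in the other 55 libraries. The surfactant proteins Sftpc (14.02 and 14.35 against 4.45) and Sftpd (14.37 and 14.42 against 4.75) and the club cell enzyme Cyp2f2 (13.99 and 14.39 against 5.34) were likewise far higher. Over 21 lung markers the median difference was 4.65 on the log2 scale (0.93 to 9.84), and 8 of the 21 were detected on none of the other arrays. Genes lower in these 2 libraries included Arg1 (a difference of -4.31), the chemokine Cxcl1 (-4.14) and the stromal proteoglycan Lum (-3.93). Young unirradiated library 5 was rich in skeletal muscle transcripts, with Acta1 at log2 14.51 against a median of 5.28 in the other young unirradiated libraries and Tnnc2 at 14.55 against 4.66. Its skeletal muscle mean was log2 13.65. Young irradiated library 1 had the next highest at 10.19, and the other 55 libraries reached at most 8.90. The first principal component held 29.3% of the variance and the second 15.1%.

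**Figure D1:**
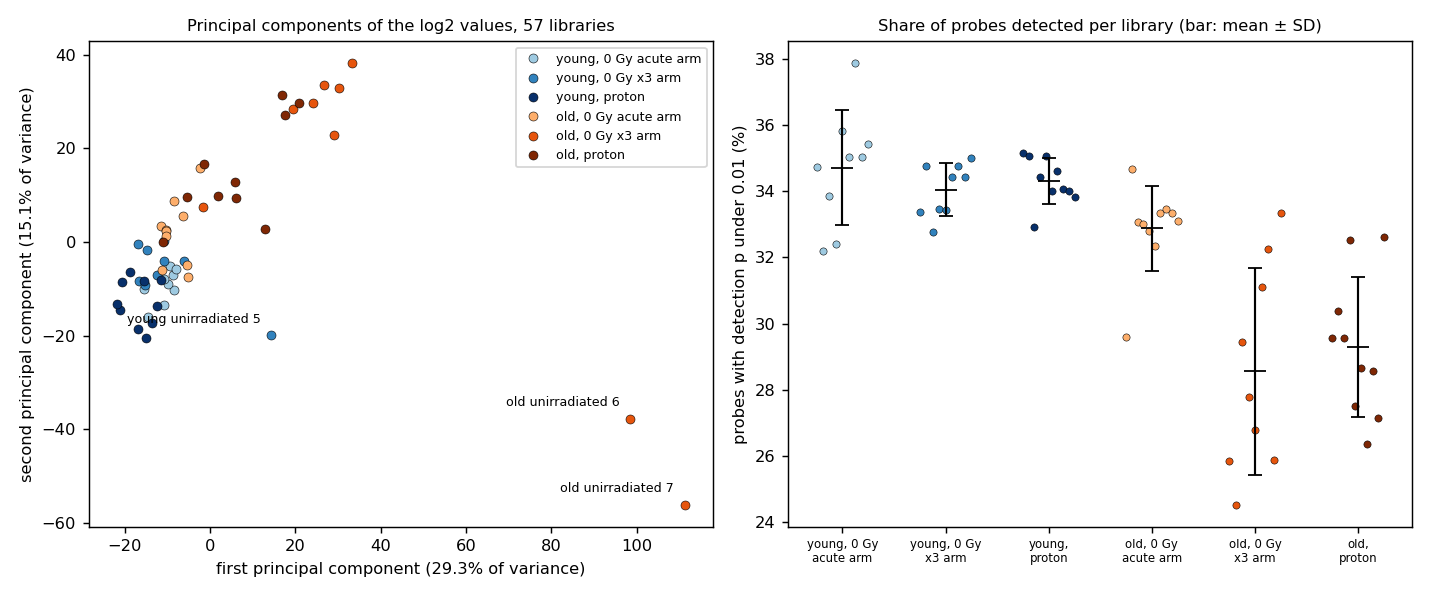
Left, each of the 57 libraries by the first and second principal components of the log2 values (percent of variance on the axes), colored by age, arm and irradiation, and right, share of probes detected per library in percent, with bars for the mean and SD of each set. Old unirradiated libraries 6 and 7 lie at 98.5 and 111.3 on the first component while no other library passes 33.2, and old x3-arm controls detect 28.6% of probes against 32.9% in old acute-arm controls.

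The first comparison asked how tumors of old mice (19 libraries) differ from tumors of young mice (18 libraries) without irradiation. Of 24 measured genes of the type I interferon response, 16 rose and 0 fell over all genes tested, and 18 rose when adjusted over the list alone (median log2 0.56, camera adjusted p = 4.87e-06; adjusted p = 0.943 with an estimated correlation). The list was called within the x3 arm (adjusted p = 3.86e-06) and not within the acute arm (adjusted p = 0.493). Usp18, the protease that takes ISG15 off proteins, was 2.35-fold higher (log2 1.23 ± 0.237 SE) and stood above the young mean in 19 of 19 old libraries. Cmpk2, a mitochondrial nucleotide kinase induced by interferon, was 2.39-fold higher (log2 1.26 ± 0.221 SE, 19 of 19), and Ifit3, an antiviral effector, 2.34-fold higher (log2 1.23 ± 0.249 SE, 18 of 19). The limma adjusted p was 6e-05 for Usp18, 1.51e-05 for Cmpk2 and 0.000116 for Ifit3. Within the acute arm it was 0.323, 0.0503 and 0.292. Without the lung-transcript libraries 6 and 7 the interferon list stayed past the threshold (adjusted p = 0.000175).

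Of 28 cell cycle genes 12 fell and 0 rose over all genes, and 13 fell adjusted over the list alone (median -0.29, camera adjusted p = 0.00325; adjusted p = 0.943 with an estimated correlation). The list was not called within the acute arm (adjusted p = 0.493) or without the lung-transcript libraries 6 and 7 (0.0836), whose cell cycle values were the lowest of the 57. Those that fell included the mitotic kinase Aurkb (log2 -0.68 ± 0.165 SE, 19 of 19), topoisomerase Top2a (-0.57 ± 0.179 SE, 15 of 19) and the replication clamp Pcna (-0.56 ± 0.152 SE, 18 of 19). Top2a stood at -0.12 within the acute arm (limma adjusted p = 0.518) and Pcna at -0.35 within the x3 arm (0.192). Of 45 oxidative phosphorylation genes 19 fell, 4 rose and 22 were not called over all genes, with 19 and 4 also adjusted over the list alone (median -0.14, camera adjusted p = 0.0241; adjusted p = 0.943 with an estimated correlation). This list too was not called within the acute arm (adjusted p = 0.614) or without libraries 6 and 7 (0.0836). Among its members Cox5a (-0.61 ± 0.105 SE, 19 of 19), Atp5d (-0.61 ± 0.0830 SE, 19 of 19) and Cox6a1 (-0.57 ± 0.154 SE, 13 of 19) fell. Cox6a1 stood at -0.08 within the acute arm (limma adjusted p = 0.613) and at -1.12 within the x3 arm. Young unirradiated library 5, with the muscle transcripts, had the highest oxidative phosphorylation mean of the 57 libraries.

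**Figure D2:**
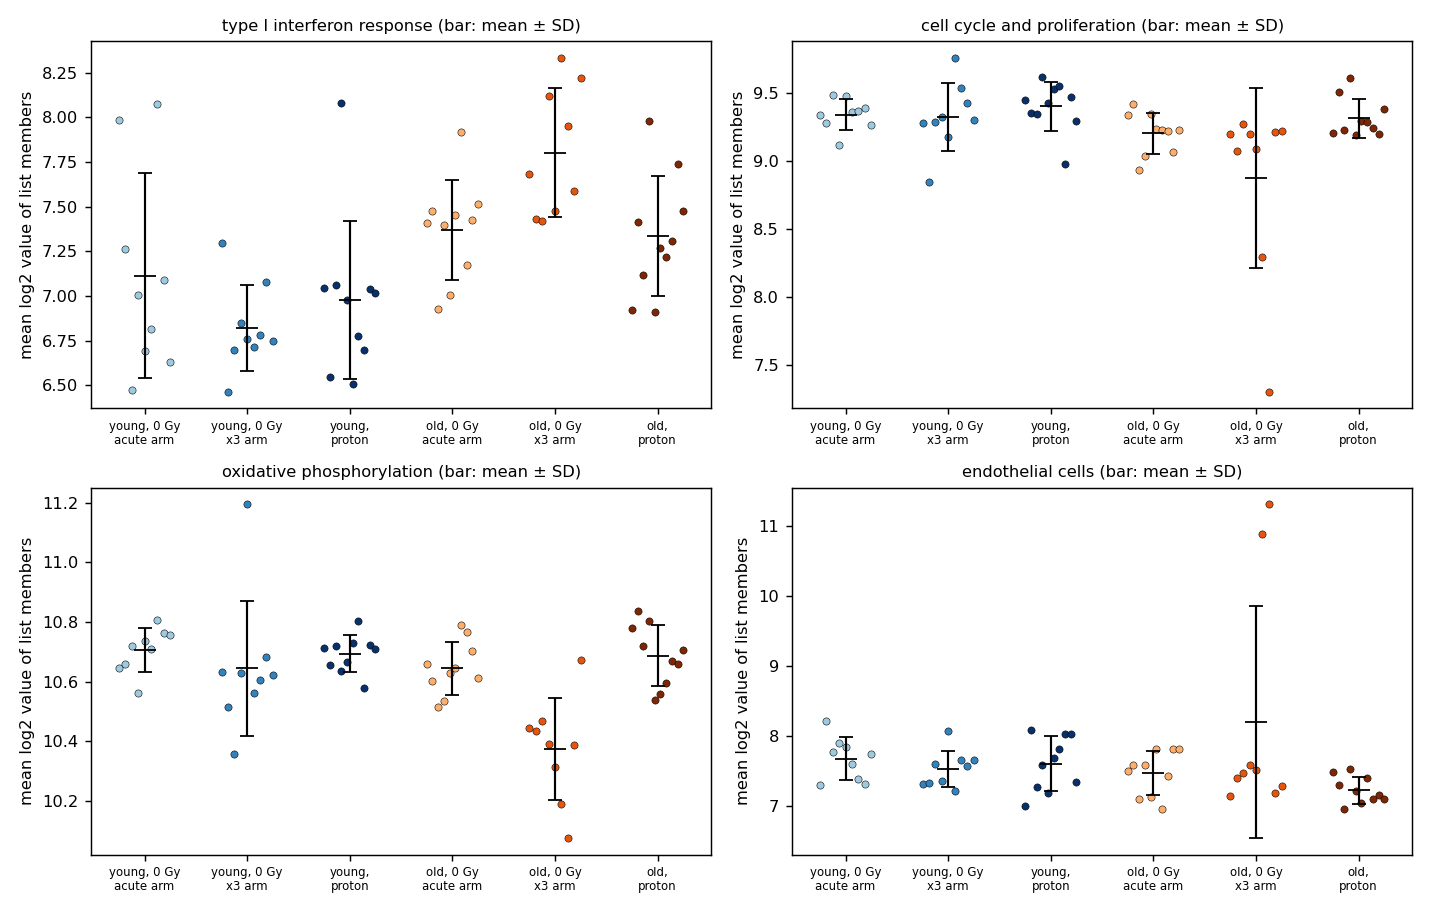
Mean log2 value of the measured members of 4 gene lists in each library, by age, control arm and irradiation, with bars for the mean and SD of each set. The interferon list lies higher in old than in young controls (median of the age effect 0.56 with all controls, not called within the acute arm), and the highest endothelial values belong to old unirradiated libraries 6 and 7. With median scaling the medians of the cell cycle and oxidative phosphorylation lists for protons in old tumors turn from 0.30 and 0.16 to -0.39 and -0.41, where the median of all genes stands at -0.55, so both lists stay above it.

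Other genes of the same sign in both control arms also differed with age. Bmx, a Tec-family tyrosine kinase, was detected in 18 of 18 young tumors and 2 of 19 old ones, so its fitted difference is not an exact fold (log2 -1.54 ± 0.131 SE, adjusted p = 4.27e-13 by limma, lower in 19 of 19). The 2 old libraries with the highest Bmx values were the lung-transcript 6 and 7. The rhomboid protease Rhbdl1 fell by 1.40 ± 0.156 SE on the log2 scale (adjusted p = 9.15e-10, 19 of 19). Among mitochondrially encoded transcripts, the complex I subunit ND4L was detected in 16 of 18 young tumors and none of 19 old ones, at least 1.22-fold lower, and the complex IV subunit COX2 was 2.35-fold lower (log2 -1.23 ± 0.221 SE, adjusted p = 2.14e-05, 19 of 19). Bmx, Rhbdl1, ND4L and COX2 were called in each control arm alone. Other large falls were those of the liver-secreted Mup2 (log2 -2.08 ± 0.532 SE), the small GTPase Arf5 (-1.55), the retinoic acid receptor Rarg (-1.34) and the integrin Itgb1 (-1.29). Arf5 (-0.46), Rarg (-0.56) and Itgb1 (-0.02, against -2.64 within the x3 arm) were not called within the acute arm. Mup2 was not called within the x3 arm (-1.73 ± 0.854 SE, limma adjusted p = 0.0955). With probes required on all arrays another probe stood for Rarg and gave 0.0208. Rises included the motor protein Myo5c (1.44 ± 0.291 SE, adjusted p = 0.000111) and the interferon-inducible Apol9a (1.33 ± 0.195 SE, adjusted p = 5.72e-07), both called in each arm, and Slfn1 (1.23 ± 0.262 SE), not called within the acute arm. Inmt, a methyltransferase abundant in lung, was higher by 1.59 ± 0.510 SE with all libraries and by 0.88 without libraries 6 and 7, and the lipid phosphatase Plpp3 by 1.21 ± 0.392 SE and by 0.64, and neither was called within the acute arm (limma adjusted p = 0.878 and 0.241). The p53 regulator Mdm2 was higher by 0.37 ± 0.0933 SE (adjusted p = 0.00149, 18 of 19) and the cytokine Tgfb1 fell by 0.62 ± 0.132 SE (adjusted p = 0.000193, 17 of 19). Within the acute arm Tgfb1 stood at -0.33 (adjusted p = 0.0536). Cdkn1a (-0.0038 ± 0.127 SE, adjusted p = 0.984) and Vegfa (0.41 ± 0.25 SE, adjusted p = 0.192) did not pass, and the proliferation marker Mki67 had no tested probe.

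In all, limma called 3561 of 9256 genes for age in unirradiated tumors, 1797 higher and 1764 lower, of which 788 changed at least 1.5-fold. With median scaling 253 were higher and 2460 lower. Without libraries 6 and 7 it called 3606, of which 2999 were shared. Within the x3 arm 4200 genes were called and within the acute arm 2604. Of the 1297 called in both arms, 499 were higher in both, 455 lower in both and 343 had opposite signs. Across genes the 2 age effects correlated with Pearson r = 0.175 and a Spearman coefficient of 0.226, where genes are not independent replicates. The share of probes detected fell with age in the same libraries, as given above, and with it as a covariate 1271 genes were called.

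**Figure D3:**
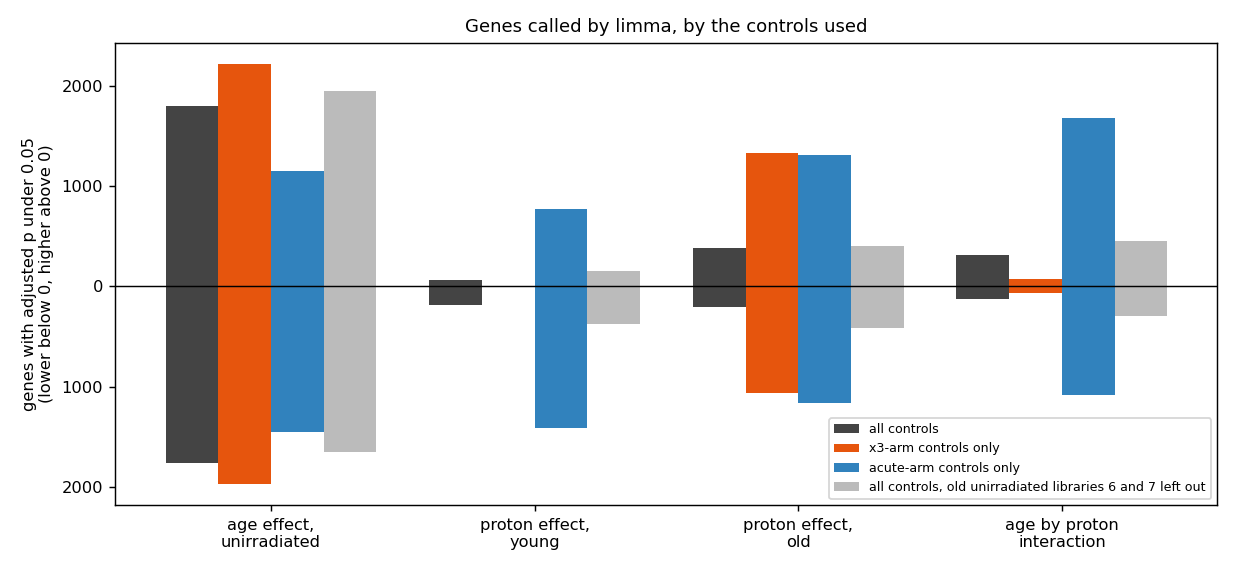
Number of genes called by limma at an adjusted p under 0.05, higher above 0 and lower below 0, for 4 comparisons, with all controls, with either control arm alone and without old unirradiated libraries 6 and 7. For protons in young tumors the count is 247 with all controls, 5 with x3-arm controls and 2184 with acute-arm controls.

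The next comparison asked what proton irradiation changed in young tumors. Relative to all 18 young controls, the 10 irradiated tumors had lower Pramel12, a PRAME-family gene (log2 -0.76 ± 0.128 SE), lower Smug1, a uracil DNA glycosylase of base excision repair (-0.75 ± 0.137 SE), and lower Zkscan14, a zinc finger gene (-0.68 ± 0.125 SE), each below the control mean in 10 of 10 libraries. The mitochondrially encoded complex I subunit ND5 was 2.25-fold higher (1.17 ± 0.282 SE, 10 of 10), and the complex IV assembly factor Surf1 1.53-fold higher (0.61 ± 0.129 SE, 10 of 10). The transcription factor subunit Gabpb1 (0.67 ± 0.161 SE), Bex2 (0.72 ± 0.153 SE), Trim35 (0.61 ± 0.145 SE) and the small nucleolar RNA Snora70 (0.63 ± 0.142 SE) were also higher in 10 of 10. Tmem53 (-0.72 ± 0.157 SE), Klhl24 (-0.69 ± 0.157 SE) and Zfp160 (-0.68 ± 0.143 SE) were lower in 10 of 10.

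Limma adjusted p was 0.000846 for Pramel12, 0.00162 for Smug1 and Zkscan14, 0.015 for ND5 and 0.00694 for Surf1. Against the 9 x3-arm controls, which match the schedule of the irradiated tumors, none of the genes named for this comparison passed. Pramel12 then stood at -0.65 ± 0.152 SE (limma adjusted p = 0.107), Smug1 at -0.43 ± 0.132 SE (0.277) and Klhl24 at -0.59 ± 0.199 SE (0.311). Cacna2d1 stood at -0.97 ± 0.235 SE (0.129) and ND5 at 0.37 ± 0.264 SE (0.669). H2bc15, a histone H2B gene (0.71 ± 0.186 SE, adjusted p = 0.0247), lost its call without young irradiated library 3, 8 or 9 (0.66 to 0.76). The Rab GTPase regulator Gdi2 (0.75 ± 0.211 SE, adjusted p = 0.0371; 0.66 to 0.80) lost it without any 1 of 14 libraries, the glucose-responsive factor Mlxipl (-0.71 ± 0.204 SE, adjusted p = 0.0415; -0.76 to -0.63) of 19, and the calcium channel subunit Cacna2d1 (-0.83 ± 0.242 SE, adjusted p = 0.0454; -0.88 to -0.72) of 21. Cdkn1a (-0.05 ± 0.152 SE, adjusted p = 0.909), Mdm2 (0.10 ± 0.112 SE, 0.716), Vegfa (0.43 ± 0.3 SE, 0.498) and Tgfb1 (-0.02 ± 0.158 SE, 0.975) did not pass.

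Genes of hypoxia and glycolysis were higher as a group in irradiated young tumors (median log2 0.29, camera adjusted p = 0.0354), though 0 of 25 members passed singly, over all genes or adjusted over the list alone, and the adjusted p = 0.979 with an estimated correlation. Antioxidant genes were higher as a group likewise, with a median of 0.15, 0 of 27 members called over all genes or adjusted over the list alone, camera adjusted p = 0.0354 and adjusted p = 0.979 with an estimated correlation. Neither list was called against the x3 arm (adjusted p = 0.0622 and 0.246) or the acute arm (0.239 for both) alone. Of the p53 targets 0 of 23 were called by limma (median -0.01, camera adjusted p = 0.935), and of the DNA repair genes 0 of 34 (camera adjusted p = 0.935), beside 1532 of 9256 genes at an unadjusted p under 0.05.

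Limma called 247 genes for protons in young tumors, 62 higher and 185 lower, of which 30 changed at least 1.5-fold. The count was 5 (0 higher, 5 lower) against x3-arm controls and 2184 against acute-arm controls, and 2 genes were called in both. Median scaling in place of quantiles left 1 gene. Single libraries moved the count by over 1.5 times: it was 102 without young irradiated library 6, 112 without 9, 115 without 8, 157 without 3 and 158 without 2, and 144, 162 and 164 without young unirradiated library 16, 12 or 10. Without old unirradiated libraries 6 and 7, which enter through the shared spread, it was 527.

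Protons were then compared with no irradiation in old tumors. The 10 irradiated tumors had lower Kmt5c, a histone H4 lysine 20 methyltransferase (1.96-fold, log2 -0.97 ± 0.124 SE), lower Prpf38b, a splicing factor (2.21-fold, -1.15 ± 0.143 SE), lower Setd5, a SET domain chromatin protein (2.71-fold, -1.44 ± 0.217 SE), and lower Dock10 (2.54-fold, -1.34 ± 0.235 SE), each in 10 of 10 libraries. Plp2 (1.77-fold, 0.82 ± 0.151 SE), the HSP70 exchange factor Hspbp1 (1.76-fold, 0.82 ± 0.169 SE), the TRAIL death receptor Tnfrsf10b (1.74-fold, 0.80 ± 0.173 SE) and the histone acetyltransferase subunit Meaf6 (1.72-fold, 0.78 ± 0.146 SE) were higher in 10 of 10. The nucleolar protein Wdr46 (0.77 ± 0.165 SE), Eef1akmt1 (0.77 ± 0.160 SE) and the clathrin adaptor subunit Ap1s1 (0.73 ± 0.159 SE) were also higher. The stress transcription factor Atf5 (-0.96 ± 0.190 SE), the sialyltransferase St8sia4 (-0.94 ± 0.249 SE) and the nuclear envelope protein Syne3 (-0.82 ± 0.182 SE) were lower. All of these genes were called by limma against each control arm alone and without libraries 6 and 7.

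Limma adjusted p was 5.15e-07 for Kmt5c and Prpf38b, 4.08e-05 for Setd5, 0.000357 for Dock10, 0.000612 for Plp2 and 0.00365 for Tnfrsf10b. Gchfr, the feedback regulator of GTP cyclohydrolase (0.82 ± 0.249 SE, adjusted p = 0.0347), lost its call without irradiated library 2, 3, 5, 8 or 10 (0.65 to 0.90), and the scaffold protein Ppp1r9a (-1.09 ± 0.311 SE, adjusted p = 0.0258) without library 8 or 9 (-1.16 to -0.91). Cdkn1a (0.01 ± 0.151 SE, adjusted p = 0.977), Mdm2 (-0.13 ± 0.111 SE, 0.517), Vegfa (-0.73 ± 0.297 SE, 0.125) and Tgfb1 (-0.27 ± 0.156 SE, 0.313) did not pass. Tgfb1 passed against acute-arm controls (-0.59, limma adjusted p = 0.000719) and not against x3-arm controls (0.10, 0.706). Cdkn1a changed its sign with median scaling (-0.66).

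**Figure D4:**
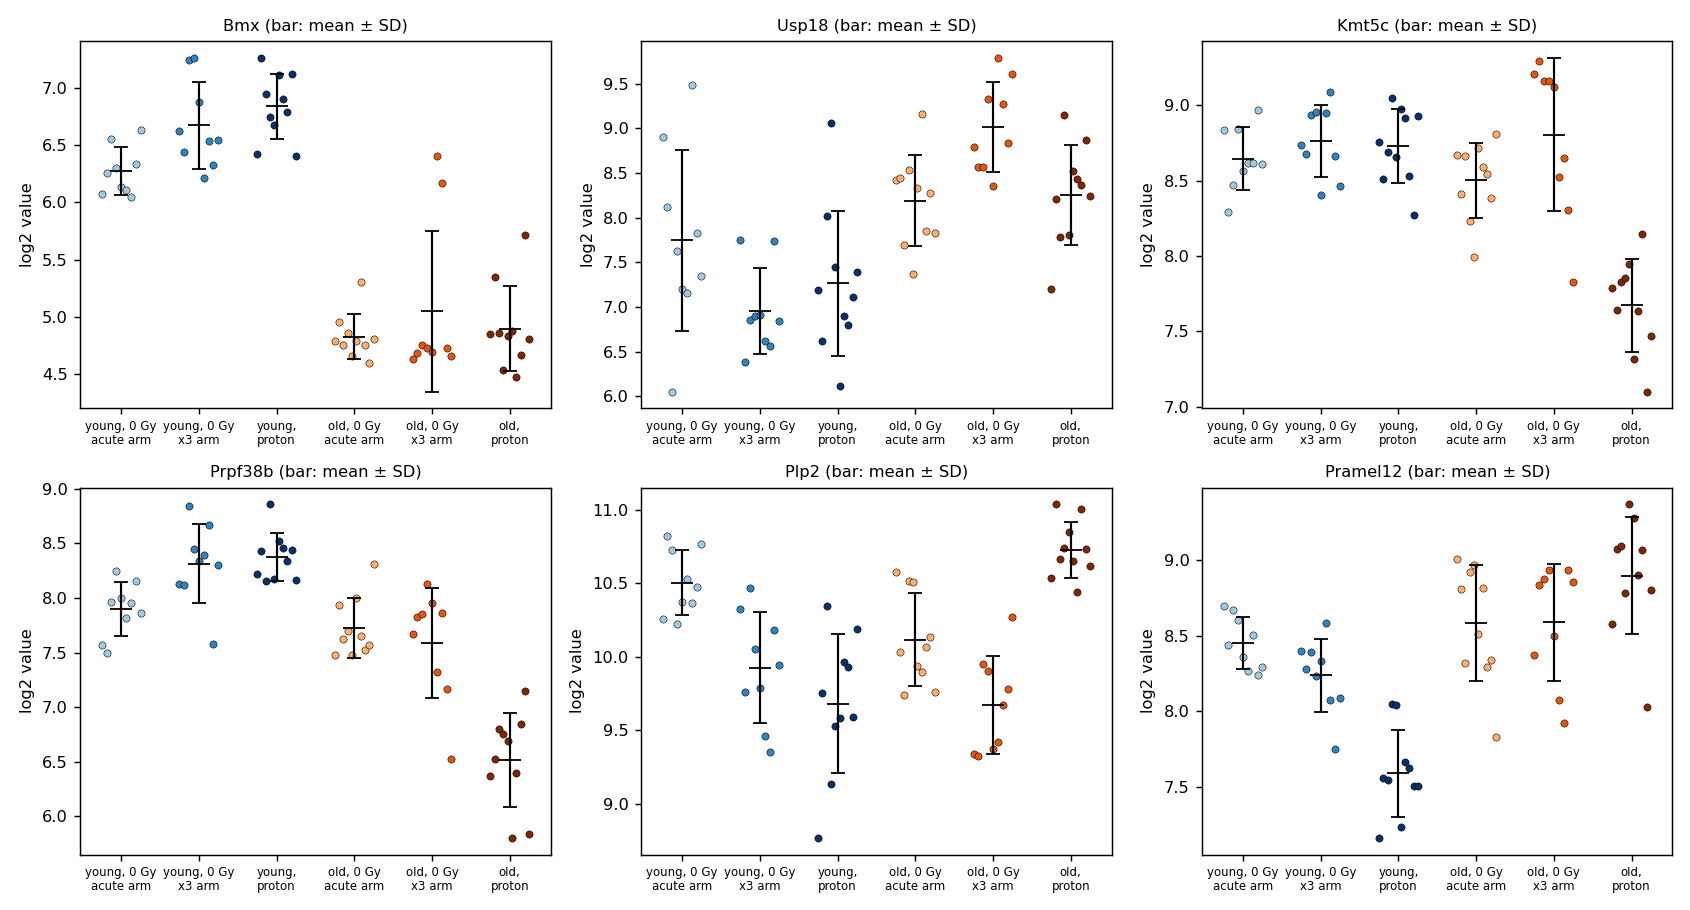
Log2 value of 6 genes in each library by age, control arm and irradiation, with bars for the mean and SD of each set. With all controls, Bmx is lower in old tumors (log2 fold change -1.54), Usp18 is higher in them (1.23), Kmt5c (-0.97) and Prpf38b (-1.15) are lower and Plp2 (0.82) higher in irradiated old tumors, and Pramel12 (-0.76) is lower in irradiated young tumors. Usp18 was not called within the acute arm, and Pramel12 was not called against x3-arm controls alone.

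Among gene groups, oxidative phosphorylation transcripts were higher in irradiated old tumors relative to all genes (median log2 0.16, camera adjusted p = 7.06e-05; adjusted p = 0.868 with an estimated correlation). That median turned to -0.41 with median scaling, where the median of all genes moved to -0.55, so the list stayed above it by 0.14. Of its 45 members 5 rose and 0 fell over all genes, and 8 rose adjusted over the list alone, among them Ndufb7 (0.65 ± 0.120 SE, limma adjusted p = 0.00072, 9 of 10), Cox6b1 (0.47 ± 0.112 SE, 0.00811, 8 of 10) and Cox6c (0.45 ± 0.122 SE, 0.0185, 9 of 10). Cox6c lost its call without irradiated library 10 (0.34), and with median scaling Cox6b1 stood at -0.10 and Cox6c at -0.21. Of 45 cytosolic ribosomal protein genes 2 rose, over all genes and adjusted over the list alone, Rps25 (0.57 ± 0.142 SE, adjusted p = 0.011) and Rpl30 (0.40 ± 0.113 SE, adjusted p = 0.0223), the latter at -0.24 with median scaling (list median 0.09 and -0.20 with median scaling, camera adjusted p = 0.00433; adjusted p = 0.868 with an estimated correlation). Rps25 stood at 0.31 against x3-arm controls (limma adjusted p = 0.0879) and Rpl30 at 0.20 against acute-arm controls (0.0653). The ribosomal list median was 0.50 in the value table of the authors, and with median scaling it stood above that of all genes by 0.34. Cell cycle genes were higher as a group with 0 of 28 called singly or adjusted over the list alone (median 0.30 and -0.39 with median scaling, camera adjusted p = 7.06e-05; adjusted p = 0.868 with an estimated correlation). The cell cycle values of the lung-transcript libraries 6 and 7 were the lowest of the 57.

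Endothelial markers were lower as a group in irradiated old tumors (median -0.59, camera adjusted p = 5.38e-05; adjusted p = 0.868 with an estimated correlation), with 0 of 19 called over all genes or adjusted over the list alone. The highest endothelial means of the 57 belonged to lung-transcript control libraries 6 and 7, and without them the median was -0.19 (adjusted p = 0.0748). Angiogenic factors and receptors had a median of -0.26 (camera adjusted p = 0.00634; 0.183 without libraries 6 and 7; adjusted p = 0.868 with an estimated correlation), and 1 of 23 fell over all genes and adjusted over the list alone, the growth factor Pdgfa (-0.51 ± 0.153 SE, limma adjusted p = 0.0327). Pdgfa lost its call without irradiated library 1, 2, 3, 4 or 8 (-0.61 to -0.46), without libraries 6 and 7 (-0.44, adjusted p = 0.0516) and against acute-arm controls (-0.41, 0.0606). The interferon list was lower as a group (median -0.22, camera adjusted p = 0.0161; 0.191 without libraries 6 and 7; adjusted p = 0.868 with an estimated correlation) with 0 of 24 called over all genes or adjusted over the list alone. Without libraries 6 and 7 the cell cycle (0.0442), oxidative phosphorylation (0.00487) and ribosomal (0.0442) lists stayed under the threshold. Against x3-arm controls alone the angiogenic (0.134) and ribosomal (0.217) lists were not called. In that fit, which holds libraries 6 and 7, 10 of 28 cell cycle genes rose and 0 fell (12 and 0 adjusted over the list alone), and 25 of 45 oxidative phosphorylation genes rose and 0 fell (27 and 1). Of 24 interferon genes 1 rose and 8 fell (1 and 9), and of 19 endothelial markers 0 rose and 9 fell (0 and 14; median -0.98). Each of these 4 lists had an adjusted p = 0.841 with an estimated correlation there. Without libraries 6 and 7 oxidative phosphorylation (adjusted p = 4.5e-05) stayed past the threshold against x3-arm controls, and cell cycle (0.159), interferon (0.128) and endothelial (0.794; median -0.17) did not. Against acute-arm controls alone none of the 6 lists was called, with adjusted p from 0.137 for ribosomal proteins to 0.934 for interferon. Of 23 p53 targets Tnfrsf10b alone rose (median -0.0016, camera adjusted p = 0.784), and of 34 DNA repair genes 3 rose and 0 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.554), beside 2044 genes at an unadjusted p under 0.05.

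Limma called 592 genes for protons in old tumors, 383 higher and 209 lower, 84 of them changed at least 1.5-fold. It called 2402 (1333 higher, 1069 lower) against x3-arm controls and 2474 against acute-arm controls. Of the 662 called against both, 183 were higher in both, 101 lower in both and 378 had opposite signs, and across genes, which are not independent replicates, the effects correlated with r = -0.0919 and Spearman coefficient -0.0696. Without libraries 6 and 7 the count was 811 (400 higher, 411 lower), of which 498 were shared. With x3-arm controls and without these libraries it was 2076 (964 higher, 1112 lower). With all controls and without irradiated library 2 it was 368. With median scaling 5828 genes were called, 0 higher and 5828 lower.

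Whether protons acted differently in old and young tumors was tested by the interaction. Prpf38b moved down in old relative to young tumors (difference of log2 changes -1.42 ± 0.203 SE, limma adjusted p = 1.65e-05), as did the histone variant gene Macroh2a1 (-0.64 ± 0.110 SE, 0.000414), which stood at -0.44 against x3-arm controls alone (adjusted p = 0.0586). Zc3h4, a zinc finger gene (0.90 ± 0.129 SE, 1.65e-05), Plp2 (1.36 ± 0.214 SE, 0.000124) and Pramel12 (1.07 ± 0.180 SE, 0.000381) moved up in old relative to young tumors. Endothelial markers (median -0.58, 0 of 19 called over all genes or adjusted over the list alone, camera adjusted p = 0.00196; adjusted p = 0.863 with an estimated correlation) and angiogenic genes (median -0.45, 0 of 23 called either way, camera adjusted p = 0.013; adjusted p = 0.607 with an estimated correlation) were lower and oxidative phosphorylation genes higher (median 0.14, and -0.48 with median scaling beside -0.62 for all genes, 5 higher and 0 lower over all genes, 7 and 0 adjusted over the list alone, camera adjusted p = 0.0443; adjusted p = 0.863 with an estimated correlation). These 3 lists were not called without libraries 6 and 7 (0.191 for each). Against x3-arm controls alone 6 lists were called. The interferon list was lower (median -0.57, 1 of 24 fell over all genes and 7 adjusted over the list alone, camera adjusted p = 2.86e-06; adjusted p = 0.677 with an estimated correlation). Cell cycle genes were higher (median 0.35, and -0.11 with median scaling beside -0.37 for all genes, 0 of 28 called either way, camera adjusted p = 0.00249; adjusted p = 0.943 with an estimated correlation). The others were oxidative phosphorylation, angiogenic, endothelial and dendritic cell genes (adjusted p = 0.357 to 0.679 with an estimated correlation). When libraries 6 and 7 were also left out, interferon (0.00029) and oxidative phosphorylation (0.000278) stayed past the threshold and the other 4 did not (0.251 to 0.659). Limma called 447 genes, 316 higher and 131 lower. Their number was 141 (73 higher, 68 lower) against x3-arm controls, 84 (30 higher, 54 lower) against these without libraries 6 and 7, and 3413 (9 higher, 3404 lower) with median scaling. It was 2774 against acute-arm controls, 750 without libraries 6 and 7, and 263, 271 and 292 without young irradiated library 9, 8 or 2.

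Among irradiated tumors, old and young differed in heat shock genes. The small chaperone Hspb1 fell by 1.85 ± 0.572 SE on the log2 scale in the 10 old tumors relative to the 10 young ones (limma adjusted p = 0.00935, 10 of 10), and the inducible HSP70 gene Hspa1a by 1.40 ± 0.412 SE (0.00648, 9 of 10). Its neighbor Hspa1b was detected in 6 of 10 young and none of 10 old tumors, at least 1.05-fold lower (adjusted p = 0.00116). Of 17 heat shock genes 8 fell and 0 rose over all genes and adjusted over the list alone (median -0.46, camera adjusted p = 0.0038; adjusted p = 0.32 with an estimated correlation). Bmx was detected in 10 of 10 young and none of 10 old tumors, at least 1.78-fold lower (adjusted p = 3.34e-12), and Tcf20 likewise, at least 1.07-fold lower (3.65e-14). Igdcc4 was detected in 9 young tumors and no old ones. Prpf38b (-1.86 ± 0.163 SE, adjusted p = 7.83e-13) and the U1 splicing protein Snrnp70 (-1.34 ± 0.123 SE, 3.34e-12) were lower in 10 of 10. Limma called 3198 genes, 1890 higher and 1308 lower in old tumors, and with median scaling 13 higher and 7667 lower. Of the 3198, 1015 were also higher and 736 also lower with age in unirradiated tumors, where lists drawn independently would share 367 and 249, and 7 and 23 had opposite signs. The share of probes detected was 29.3% in the old and 34.3% in the young irradiated tumors, and with it as a covariate 1462 genes were called.

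Irradiated old tumors were also set against unirradiated young ones, the contrast of both factors together. The chemokine Cxcl10 was 2.37-fold higher (1.24 ± 0.281 SE, limma adjusted p = 0.000576, 9 of 10), Ifit3 2.02-fold (1.02 ± 0.299 SE, 0.00734, 9 of 10) and Usp18 1.88-fold (0.91 ± 0.285 SE, 0.0119, 9 of 10), though Usp18 stood at -0.08 with median scaling, where the median of all genes moved to -0.80. Of 24 interferon genes 5 rose and 0 fell over all genes and adjusted over the list alone (median 0.37 and -0.47 with median scaling, camera adjusted p = 0.0347; adjusted p = 0.95 with an estimated correlation). Hspa1a fell by 1.46 ± 0.363 SE (adjusted p = 0.00157) and Hsf2, a heat shock factor, by 0.53 ± 0.156 SE (0.00755), and of 17 heat shock genes 6 fell and 0 rose, or 8 and 0 adjusted over the list alone (median -0.44, camera adjusted p = 0.00792; adjusted p = 0.472 with an estimated correlation). Hspa1b was detected in 9 of 18 young unirradiated tumors and in none of the 10 old irradiated ones. Of 45 ribosomal protein genes 10 rose and 0 fell, or 9 and 0 adjusted over the list alone (median 0.12 and -0.32 with median scaling, camera adjusted p = 0.00792; adjusted p = 0.95 with an estimated correlation). Among them Rpl29 (0.47 ± 0.107 SE, adjusted p = 0.000574), Rpl21 (0.57 ± 0.153 SE, 0.00378) and Rps25 (0.50 ± 0.144 SE, 0.00588) stood at -0.07, -0.42 and -0.18 with median scaling, and Rpl21 and Rps25 at -0.0135 and -0.0847 with the share of probes detected as a covariate. The ribosomal list median was 0.67 in the value table of the authors, and with median scaling it stood above that of all genes by 0.48. Against the acute arm alone none of the 3 lists was called (0.202 for ribosomal and heat shock genes, 0.469 for interferon). Against that arm Ifit3 stood at 0.66 (limma adjusted p = 0.103) and Usp18 at 0.51 (0.211), and against x3-arm controls Hsf2 at -0.39 (0.144) and Rps25 at 0.30 (0.114). Tgfb1 fell by 0.89 ± 0.158 SE (adjusted p = 2.17e-05, 10 of 10), while Cdkn1a (0.01 ± 0.152 SE, 0.976; -0.82 with median scaling), Mdm2 (0.24 ± 0.112 SE, 0.0951; -0.51 with median scaling) and Vegfa (-0.32 ± 0.3 SE, 0.447) did not pass. Mdm2 passed against acute-arm controls alone (0.30, limma adjusted p = 0.0109). Limma called 2838 genes, 1524 higher and 1314 lower, and with median scaling 14 higher and 7882 lower.

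The unirradiated controls themselves differed between arms. In old tumors the mitochondrial phosphate carrier Slc25a3 was lower in the x3 arm than in the acute arm (log2 -1.70 ± 0.130 SE, limma adjusted p = 1.42e-14), as were the transcription factor Nfya (-1.56 ± 0.134 SE, 5.97e-13), the tetraspanin Tspan3 (-1.90 ± 0.163 SE, 5.97e-13) and the mRNA export factor Alyref (-1.93 ± 0.173 SE, 1.86e-12), each below the acute-arm mean in 9 of 9 libraries. The cochaperone Dnajc7 was higher (1.17 ± 0.107 SE, 3.72e-12 by limma, 9 of 9). Limma called 4619 genes between the old arms, 2320 higher and 2299 lower, and 4270 without libraries 6 and 7, of which 3466 were shared. With median scaling 169 were higher and 5062 lower. In young tumors it called 1300 (469 higher, 831 lower), with Kansl3 (-0.69 ± 0.0794 SE), the mRNA export receptor Nxf1 (-0.67 ± 0.0835 SE), Tbc1d13 (-0.73 ± 0.0913 SE) and Sec16a (-0.64 ± 0.0869 SE) lower and Acap2 (1.02 ± 0.138 SE) higher in 9 of 9 x3-arm libraries. In old x3-arm controls hypoxia and glycolysis genes (median -0.54, 1 higher and 12 lower of 25 over all genes and adjusted over the list alone, camera adjusted p = 0.0496), oxidative phosphorylation genes (-0.28, 5 higher and 20 lower of 45 or 7 and 20 adjusted over the list alone, 0.0354) and cell cycle genes (-0.26, 0 higher and 13 lower of 28 or 0 and 12 adjusted over the list alone, 0.0496) were lower, and endothelial markers were higher (0.58, 8 higher and 0 lower of 19 both ways, 0.0496). Each had an adjusted p = 0.973 with an estimated correlation, and none was called without the lung-transcript libraries 6 and 7 (0.108 to 0.781).

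The relation between the age effect and the proton effect was taken across genes with separate control arms, so that no control array was shared. The age effect within the acute arm and the proton effect against x3-arm controls correlated with r = -0.0578 ± 0.117 (jackknife SE over arrays; Spearman coefficient -0.103) in young and r = -0.0291 ± 0.0937 (Spearman coefficient -0.0943) in old tumors across 9256 genes, which are not independent replicates. With the arms exchanged r was -0.272 in young and 0.519 in old tumors. Of genes called in both comparisons with all controls shared, 142 were lower with age and higher with protons in old tumors, where independent lists would share 73.0, but both effects then use the same control arrays. The F-test of limma over the 4 groups called 5156 genes.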

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

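Some tests in this part were chosen after the result was seen. These were on the libraries with lung transcripts, their part in the arm difference and the arm schedule. Also among them were the interferon list without libraries 6 and 7 or within the acute arm and the splits within the x3 arm. Predictions for array signal in the arm difference and the interferon list, and for the other splits, were written before their results. The detected share as a covariate and the leaving out of libraries 6 and 7, which the array-signal tests use, were chosen after seeing the data. All patterns weighed here were found in the same data and stand as hypotheses.

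Old unirradiated libraries 6 and 7 stand apart from the other 55. A candidate explanation is lung tissue in these 2 tumor pieces: the markers listed for lung were higher by a median of 4.65 (log2), led by Scgb1a1 (9.84 higher) and Sftpc (9.71 higher), and 3 of the markers, Abca3, Hopx and Napsa, were detected on all other libraries too. Low array signal is argued against, because 15 libraries had a lower share of probes detected and none of these passed 33.2 on the first component, where the 2 libraries lay at 98.5 or above. Age of the mice is argued against as well, because the other 27 old libraries differed from the 28 young ones by a median of 0.114. If it is lung tissue, whether it was taken with the tumor, came from a tumor grown in lung or was mixed in later was not tested. Nor was it tested whether these 2 libraries are lung samples rather than tumor pieces.

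The old x3-arm controls differ from the old acute-arm controls in 4619 genes, and the lung-transcript libraries are excluded as the whole cause, since 4270 genes were called without them. Lower array signal stays open: over the 10 old irradiated libraries the position along the arm difference (0.0238 to 0.839, 0 at the acute arm and 1 at the x3 arm) had r = -0.408 with the share of probes detected (permutation p = 0.241, adjusted p = 0.367; Spearman coefficient -0.321, permutation p = 0.367; r = -0.196 without the 2 farthest libraries). With that share in the fit and libraries 6 and 7 left out 1156 genes were called, 1053 of them among the 4270 and in the same direction, as the spread of the log2 differences went from 0.481 to 0.388 and the median SE rose from 0.139 to 0.179, while with all 57 libraries the same term gave 3902 genes, 3053 of them among the 4619 and in the same direction (spread 0.562 and 0.62, median SE 0.146 and 0.174), so the answer turns on those 2 libraries. Day, batch or schedule may also be the cause, since 1300 genes differed between the arms in young tumors too. The non-normalized negative-control level also parted the young arms, at 84.8 to 112 in x3-arm and 129 to 144 in acute-arm controls. In old x3-arm controls it was 110 to 139, and in old acute-arm controls 114 to 195. Irradiated arrays stood at 88.3 to 130 in young and 110 to 137 in old tumors. Arm, mice and handling are confounded, however, and 1 label field of 9 old acute-arm controls names no dose. A biological difference between the sets of mice stays open and untested.

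Type I interferon genes were higher as a list in old unirradiated tumors at the preset correlation of camera, on which the tests here also rest, and the list did not pass with an estimated correlation (adjusted p = 0.943). The lung-transcript libraries are excluded as the whole cause of the call at the preset correlation, since the camera adjusted p was 0.000175 without them. Lower array signal is argued against as the whole cause: with the share of probes detected in the fit and libraries 6 and 7 left out, the list median was 0.571 (quartiles 0.372 to 0.854; adjusted p = 1.33e-07) against 0.515 without that term. Age of the mice stays among the open explanations, since within the acute arm the list was not called (adjusted p = 0.493) and within the x3 arm it cannot be told apart from whatever else differs between the sets of animals.

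Whether chance can be excluded was examined with 100 splits of each comparison, the real one included. In these comparisons 1 split, the real one, gave as many genes: age in unirradiated tumors (3561 genes, highest other split 16), protons in young tumors (247, highest other 1), age in irradiated tumors (3198, highest other 5), irradiated old against unirradiated young tumors (2838, highest other 35), the 4 groups together (5156, highest other 18), the young control arms (1300, highest other 204) and the old control arms (4619, highest other 2056). This argues against chance for these counts, though 100 splits cannot show less than 1 in 100. For the interaction 1 split, the real one, also gave as many genes (447, highest other 287). Chance is not excluded there, because splits among the x3-arm controls and irradiated tumors passed the real count, as given below. For protons in old tumors 3 of the 100 splits gave as many as the real 592 and the highest other gave 1520. A split that calls so many more genes than the real one points to a structure among the old samples other than irradiation, and the control arms and the 2 lung-transcript libraries are such structures. All irradiated tumors have the x3 schedule and the controls come from both arms, so these splits do not part irradiation from arm. Among the irradiated tumors and x3-arm controls alone, 1 of 100 splits, the real one, gave as many genes for protons in young and in old tumors. The counts were 5 (highest other split 3) and 2402 (highest other 2068). For the interaction 2 splits gave as many as the real 141 and the highest other gave 462, which again points to a structure other than irradiation. These splits were chosen after the result was seen, and other splits came near or passed the real counts, so they do not exclude chance.

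Of 77 sets of values from the 10 libraries of an irradiated group, 4 held a library far from the others, where chance gives about 1 in 20. Prpf38b stood at 8.86 in young irradiated library 4 (others 8.15 to 8.52), Igdcc4 at 4.98 in young irradiated library 10 (others 5.41 to 5.78), Cox6c at 11.65 in old irradiated library 10 (others 10.21 to 10.97) and Hsf2 at 6.53 in old irradiated library 6 (others 4.55 to 5.55).

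The proton effect differed between ages by the interaction test with all controls for 27 named genes. Against x3-arm controls alone that test called 141 genes in place of 447, and 84 when libraries 6 and 7 were also left out. The change in old minus that in young tumors was positive (log2) for Mup2 (3.07), Sec16a (0.53), Pramel12 (1.07), Smug1 (0.85), Tmem53 (1.02), Mlxipl (1.05), Zfp160 (0.71), Zkscan14 (0.71), Gchfr (1.53), Plp2 (1.36), Meaf6 (0.91), Wdr46 (0.89), Eef1akmt1 (1.17), Ndufb7 (0.61), Cox6c (0.77) and Zc3h4 (0.90). It was negative for Gdi2 (-1.13), Gabpb1 (-1.20), Trim35 (-0.90), Setd5 (-1.78), Dock10 (-1.30), Prpf38b (-1.42), Kmt5c (-0.997), Atf5 (-1.22), Syne3 (-1.12) and Macroh2a1 (-0.64). For Igdcc4 the fitted difference (-0.36) is not an exact value, since the gene was detected on none of the 10 old irradiated arrays. Most were named for a proton effect in 1 age, which favors a difference between ages. Zc3h4 and Macroh2a1 were named for their small p-values in the interaction test itself, so their calls here add no support. Mup2 and Sec16a were named for differences among unirradiated tumors, and those arrays enter their values here too. Igdcc4 was named for the age effect in irradiated tumors, whose arrays likewise enter its value. As lists, angiogenic factors and receptors (-0.45), oxidative phosphorylation (0.14) and endothelial markers (-0.58) differed by camera at the preset correlation, and none of the 3 did with an estimated correlation (adjusted p = 0.607 to 0.863) or without libraries 6 and 7 (0.191 for each). With median scaling the oxidative phosphorylation median stood at -0.48 and that of all genes at -0.62, so the list stayed above it by 0.14. Outside the tested genes, the probe of Sftpc, which the detection filter removed, was 9.71 higher in old unirradiated libraries 6 and 7 than in the other 55.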

How the results depend on the processing

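Chosen after seeing the data were the fits without old unirradiated libraries 6 and 7, without these and young unirradiated library 5, with the share of probes detected as a covariate, and with x3-arm controls but without libraries 6 and 7; the other alternatives were fixed before. Of named genes, 1406 of the values under alternatives kept their direction and side of the threshold, 170 fell short of it, 10 newly passed and 13 turned, 10 of these with median scaling, which moved all genes (medians below), and of called lists 42 were kept and 47 lost. Genes named as largest rises or falls had to keep their sign against each control arm, so they could not turn under those settings. The 1.5-fold setting keeps the main value and cannot turn either. Over all genes, signs were opposite for 343 of the 1297 called in both arms for age. For protons they were opposite for 378 of 662 in old and 0 of 2 in young tumors. Signal over background limits dim genes: without the probe filter 19057 genes were tested. The cause was not tested unless given. Chips as a block were not run, because the files used here give no chip numbers. The count for the old control arms stayed within 1.5 times under the refits run for it. It was 2167 with a minimum change of 1.5-fold, and 1156 with the share of probes detected as a covariate and libraries 6 and 7 left out together.

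For age in unirradiated tumors the count of 3561 became 6066 with no probe filter (more genes tested), 788 with a minimum change of 1.5-fold and 1271 with the share of probes detected as a covariate. For protons in young tumors 247 became 376 in the value table of the authors (48 higher, 328 lower), 1 with median scaling, 1516 with array weights, 663 with only the groups compared, 5 with x3-arm and 2184 with acute-arm controls, 30 with a 1.5-fold minimum, 527 without libraries 6 and 7, 622 also without young library 5, and 20 with x3-arm controls without 6 and 7. For protons in old tumors 592 became 5828 with median scaling, 2128 with array weights, 234 with only the groups compared, 2402 with x3-arm and 2474 with acute-arm controls, 84 with a 1.5-fold minimum, 1209 with the detected share and 2076 with x3-arm controls without 6 and 7. For the interaction 447 became 3413 with median scaling, 2429 with array weights, 141 with x3-arm and 2774 with acute-arm controls, 750 without 6 and 7, 824 also without young library 5 and 84 with x3-arm controls without 6 and 7. For age in irradiated tumors 3198 became 7680 with median scaling, 5917 with no filter and 1462 with the detected share. For irradiated old against unirradiated young tumors 2838 became 7896, 5267 and 1160 under the same settings. The young arms went from 1300 to 50 with median scaling and 2525 with array weights. With a 1.5-fold minimum the count was 258 for the interaction, 1396 for age in irradiated tumors and 289 for the young arms. For irradiated old against unirradiated young tumors it was 848. The F-test count of 5156 became 8079 with median scaling, 8713 with no filter, 1045 by ANOVA with Bonferroni correction and 3164 with the detected share.

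With the replicate number as a block the counts were 436 for protons in young tumors, 1387 for protons in old tumors and 1681 for irradiated old against unirradiated young tumors; these numbers do not pair the samples, since 6 of 68 same-number pairs were best matched with their own number.

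Leaving out 1 library at a time gave 3275 to 3751 genes for age, 102 to 325 for protons in young tumors, 368 to 757 for protons in old tumors, 263 to 634 for the interaction, 2843 to 3383 for age in irradiated tumors and 2393 to 2890 for irradiated old against unirradiated young tumors.

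The median of all genes, -0.01 to 0.04 without it, stood with median scaling at -0.25 for age, -0.55 for protons in old tumors, -0.62 for the interaction, -0.86 for age in irradiated tumors, -0.80 for irradiated old against unirradiated young tumors and -0.54 for the old arms, so directions there are relative to these medians. With it, in irradiated old tumors, Cox6b1 turned to -0.10, Cox6c to -0.21, Rpl30 to -0.24 and Cdkn1a to -0.66. Against unirradiated young tumors Cdkn1a turned to -0.82, Mdm2 to -0.51, Rpl21 to -0.42, Rps25 to -0.18, Rpl29 to -0.0664 and Usp18 to -0.084. With the detected share as a covariate Rpl21 turned to -0.0135 and Rps25 to -0.0847. Rarg for age turned to 0.0208 with the filter on all arrays, where another probe stands for the gene.

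The relation between age and proton effects in young tumors went from r = -0.058 to -0.272 with the arms exchanged (-0.256 also without 6 and 7). In old tumors it went from -0.029 to 0.519 with the arms exchanged (0.546 without 6 and 7), -0.303 with all controls shared (-0.136 without 6 and 7) and -0.147 without 6 and 7. Simulated unchanged groups that share controls gave -0.400 in old tumors, but a covariance of -0.00802 against -0.0266 in the data. Sharing alone thus gave a smaller covariance than the data with all libraries. Without libraries 6 and 7 the covariance in the data was -0.00975, near the simulated value. The excess over sharing therefore rests largely on those 2 libraries. In young tumors r was -0.0851 with all controls shared, where simulated unchanged groups gave 0.418. The covariances there were small, -0.00621 in the data (-0.00213 without 6 and 7) and 0.00837 in the simulation.

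The counts here are of all lists under the threshold in a setting, whether or not called in the main fit. Camera with an estimated correlation called 0 for age, 0 for protons in young, 0 for protons in old tumors, 0 for the interaction, 0 for age in irradiated tumors and 0 for irradiated old against unirradiated young tumors. Fry called 0 for protons in young, 0 in old tumors, 0 for the interaction and 3 for age in irradiated tumors. Without 6 and 7 there was 1 for age, 1 for the interaction and 2 for age in irradiated tumors. X3-arm controls gave 1 for protons in young tumors and 6 for the interaction, and the value table of the authors 6 for the interaction and 1 for irradiated old against unirradiated young tumors.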

Other observations

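Beyond the lists described so far, members of several groups moved with age in unirradiated tumors without a call for the list by camera. Of 34 DNA repair genes 6 rose and 12 fell by limma over all genes, or 6 and 13 adjusted over the list alone (median -0.07, camera adjusted p = 0.595). Of 27 genes of collagens and extracellular matrix 1 rose and 8 fell, also adjusted over the list alone (median -0.07, 0.503). Of 17 heat shock genes 5 fell and 0 rose, also adjusted over the list alone (median -0.29, 0.103), the direction seen among irradiated tumors. Genes of the unfolded protein response went both ways, 5 higher and 7 lower of 23, or 5 and 8 adjusted over the list alone (median -0.11, 0.636), as did 18 genes of epithelial-mesenchymal transition, 5 higher and 5 lower, or 8 and 5 adjusted over the list alone (0.648). Of 23 p53 targets 6 rose and 2 fell, also adjusted over the list alone (median 0.12, 0.595).

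No cell type list was called by camera for age in unirradiated tumors. Of 5 peripheral nerve markers 3 rose, also adjusted over the list alone (median 0.25, camera adjusted p = 0.0538). Of 8 MHC class II genes 0 were called by limma over all genes or adjusted over the list alone at a median of 0.61 (0.488), beside 4405 genes at an unadjusted p under 0.05. Macrophage markers (2 higher and 1 lower of 22, 0 adjusted over the list alone, median -0.0058, 0.859), fibroblast markers (1 higher and 2 lower of 14, also adjusted over the list alone, median 0.0059, 0.929) and neutrophil markers (0 of 10 either way, median -0.04, 0.929) had medians near 0. For protons against x3-arm controls alone in young tumors, collagens and extracellular matrix were the 1 list called (median 0.31, camera adjusted p = 0.00388; adjusted p = 0.877 with an estimated correlation). It was higher as a group with 0 of 27 members called by limma over all genes or adjusted over the list alone, beside 933 genes at an unadjusted p under 0.05.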
